A study of Homo sapiens with 8 samples.

How the data were processed

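Polyadenylated RNA from 4 control pulmonary arteries, 3 CTEPH pulmonary arteries and 1 aorta had been made into libraries with a standard Illumina protocol, per the labels. The labels' extraction text names RNA from mouse kidney, while the organism is given as human and the gene identifiers in the files are human Ensembl identifiers, so the extraction text was not relied on. Reads were processed with STAR 2.5.1b and HTSeq on GRCh38, per the submitters' processing notes; the HTSeq version and the gene annotation release are not given in the sources used here. For each library the authors deposited a table of whole-number counts per gene in the layout of STAR's gene counts, with 60675 gene identifiers, 1 unstranded and 2 stranded count columns and 4 rows that name no gene. In STAR's layout, reads that map to several places are not counted for a gene, which lowers the counts of genes with near-identical copies. Rows naming no gene held 14.6% to 20.2% of each library's total and were left out of library sizes and tests.

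One stranded column held 94.1% to 95.0% of the counts of both stranded columns in every library and was used (file column 4), by a rule that required 80%. Genes of the Y chromosome, XIST and TSIX (517 in all) were left out of library sizes and tests. Symbols, coordinates and gene types came from GENCODE 29 on GRCh38, which matched 57055 of the 60675 identifiers. Total counts used ranged from 22992214 to 50391827 per library. Samples were grouped by the sample type label, and replicate numbers only name libraries and pair nothing. Within a group, chi-square per degree of freedom between libraries over genes with at least 20 summed counts was 53.6 or more, so no pair agreed within sampling noise.

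CTEPH and control libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes scaled by TMM, and the robust quasi-likelihood test adjusted by the Benjamini-Hochberg method with a threshold of 0.05, with no covariates and without the aorta. Standard errors are the fitted log2 fold change divided by the square root of F. CPM means are TMM-scaled and given with their SD. A total of 33 gene lists were fixed before the data were examined. Of these, 32 were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, at least 5 tested members), and 1 list, of regional identity factors, was kept for the aorta. For a gene with 0 counts in a group, the fold was set against a floor of 3 counts over that group. With 1 to 3 counts, the ratio of pooled counts is given with an exact binomial 95% interval. These intervals cover counting error only. The aorta was described by the difference of log2 CPM (prior count 2) from the control mean.

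Named genes followed rules fixed before the data were examined. For the largest changes these were the 10 highest and 10 lowest fold changes among called protein-coding genes with at least 2 CPM in the higher group and no overlap between groups. For each list they were up to 3 called members with the lowest p, or 2 members as values where none was called. For the aorta they were 8 genes in each direction outside all 7 pulmonary artery libraries with at least 5 CPM. Immunoglobulin, T cell receptor and HLA genes, genes with common germline deletions and genes without an approved-style symbol were excluded from the first and the last rule. MYH11, VWF and PLVAP were added after their values were seen. Some genes that the rules name are not reported here.

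The tests were checked on simulated counts for 15388 genes of the CTEPH comparison, drawn with the real means, dispersions and library sizes. Of 50 genes each, the edgeR test recovered 74% raised and 50% lowered 4-fold, and 10% raised and 0% lowered 2-fold. Changes of 2-fold were thus mostly missed in this simulation. Of 76 calls 6 were false (7.89%), against 42 of 165 (25.5%) with DESeq2 and 5 of 71 (7.04%) with limma-voom. Only 200 single genes and 1 list were changed, while edgeR made 1740 calls in the real libraries. The adjusted threshold was therefore stricter in the simulation, and these rates do not carry over to the real comparison. A list shifted by 1 log2 unit was recovered by camera with both correlations, and 0 of 31 other lists were called. The simulated genes were drawn independently of one another, without the correlation that members of a list can have. The 0 of 31 therefore does not show how often camera calls lists by error in the real libraries. For the aorta description, a simulated shift of 1 in a list of 30 among 17631 genes gave a median of 1.02.

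Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library sizes only, no filter, at least 2 CPM in 3 libraries, the unstranded column, glmTreat at 1.5-fold, all 8 libraries in the fit, 1 surrogate variable (sva 3.50.0), removal of haemoglobin and mitochondrial genes, and each library left out in turn. For lists, an estimated correlation and fry were added. For the aorta they were a prior count of 0.5, library sizes only, another filter and each control left out.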

Results

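Polyadenylated RNA of human arteries was sequenced to compare pulmonary arteries in chronic thromboembolic pulmonary hypertension (CTEPH) with control pulmonary arteries. In CTEPH, organised clots narrow the pulmonary arteries and raise the pressure in them. The controls came from healthy failed donors, per the labels. The 8 libraries comprised 4 control pulmonary arteries, 3 CTEPH pulmonary arteries and 1 aorta whose disease state the labels do not give. The design text also names idiopathic pulmonary arterial hypertension, which was not analysed here. Counts assigned to genes totalled 27814128, 50391827, 24539622 and 47259150 in Control 1 to 4. They totalled 22992214, 25366137 and 32140146 in CTEPH 1 to 3 and 26733738 in the aorta. Between 19760 and 21209 genes had at least 1 count in a library. The labels do not say that the libraries of a group came from separate donors, so the p-values below measure the spread between these samples. They also do not say which segment or which layers of the artery were taken.

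The first comparison asked which transcripts differ between CTEPH and control pulmonary arteries. All 16 adipocyte and all 11 Schwann cell markers tested fell in the CTEPH arteries, as did 9 of 13 mesothelial or lymphatic, 10 of 19 macrophage and 9 of 20 complement genes. With an estimated correlation none of these lists passed (adjusted p = 0.229, 0.0598, 0.0598, 0.338 and 0.338). In the endothelial, interferon-response and mast cell lists 10 of 19, 9 of 23 and 3 of 11 genes rose, and these lists did not pass either (adjusted p = 0.456, 0.338 and 0.338 with an estimated correlation). Contractile smooth muscle genes as a list did not pass the test, with the smooth muscle myosin gene MYH11 at 21470 ± 17974 CPM (SD, n = 4) in control and 26466 ± 4877 CPM (SD, n = 3) in CTEPH arteries. Of 15696 genes tested with edgeR's quasi-likelihood test, 1740 had a Benjamini-Hochberg adjusted p under 0.05, 614 of them higher and 1126 lower in CTEPH. At least a 2-fold change was fitted for 444 of the higher and 946 of the lower genes. Among the called genes, 613 were higher in all 3 CTEPH libraries than in any of the 4 controls, and 1123 were lower in all. Such a separation was seen in 28.3% of all tested genes, against 5.71% expected by chance. The first principal component held 53.7% of the variance and parted the groups, with controls between -79.9 and -45.9 and CTEPH libraries between 75.7 and 92.3. Correlations of log2 CPM across genes were 0.918 to 0.958 between controls, 0.964 to 0.970 between CTEPH libraries and 0.862 to 0.9002 across the groups. The count of called genes fell to 652, 552 and 430 when CTEPH 1, 2 or 3 was left out. It was 764 when a change beyond 1.5-fold was required and 3322 with DESeq2.

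The 10 largest increases were in genes that averaged at most 1.22 CPM in control arteries. SULT1E1, the oestrogen sulfotransferase gene (ENSG00000109193, chromosome 4, 69841212 to 69860152, GRCh38), had 1 count over the 4 controls and 249 over the 3 CTEPH libraries, with an edgeR adjusted p of 0.00154. Its pooled count ratio was 422, with a 95% counting interval of 75.02 to 16727, and without Control 4, which held the 1 count, the gene was at least 97.4-fold higher against a floor of 3 counts over the remaining controls. PRSS3, which encodes a trypsinogen, had 3 and 376 counts, a ratio of 212 (72.1 to 1034), and its reads can be shared with other trypsinogen genes. Without CTEPH 1 only 103 of the 376 counts remained and the ratio was 81.9 (27.2 to 403), and it was 320.3 without CTEPH 3, 517 without Control 3 and 17.3 (11.7 to 26.8) in the unstranded counts. RXFP1, the receptor of the vasodilator hormone relaxin (chromosome 4, 158315311 to 158653372), averaged 0.0260 ± 0.0323 CPM (SD, n = 4) in controls and 2.36 ± 1.39 CPM (SD, n = 3) in CTEPH, a 75.2-fold change that was 161-fold without Control 4. PDE4C, a cyclic AMP phosphodiesterase gene (chromosome 19, 18208652 to 18248200), rose from 0.625 ± 0.180 to 33.6 ± 15.4 CPM, a log2 fold change of 5.75 ± 0.45 (SE), and 5.02 in the unstranded counts. DKK2, a modulator of Wnt signalling (chromosome 4, 106921802 to 107283806), rose from 1.04 ± 0.539 to 45.2 ± 20.7 CPM, a 43.7-fold change (adjusted p = 0.00219). NECTIN4, an adhesion molecule gene, rose 60.6-fold (29.4-fold without CTEPH 1), and SLC30A3, a zinc transporter gene, 52.4-fold (88.2-fold without Control 1 and 30.97-fold without CTEPH 2). LYPD2 rose 47.6-fold (129-fold without Control 3) and CSMD1 45.5-fold (118-fold without Control 4 and 24.5-fold in the unstranded counts). DMP1, which encodes a mineralised-matrix protein, rose 38.2-fold to a CTEPH mean of 47.7 ± 71.2 CPM. CTEPH 1 had 7.02 log2 CPM and the others 2.58 and 2.89, with 5.39-fold left without that library (adjusted p = 0.0876), and 60.5-fold without Control 4. The call of DMP1 was lost in 10 of 21 alternative settings, among them the fits without Control 1, 2, 3 or 4 and without CTEPH 1 or 3 (adjusted p at most 0.141). LYPD2 lost its call without CTEPH 1, 2 or 3 (adjusted p at most 0.058) and CSMD1 without CTEPH 3 (0.0568).

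The 10 largest decreases were in genes that averaged at most 0.418 CPM in CTEPH arteries. ADIPOQ, the adipocyte hormone adiponectin (ENSG00000181092, chromosome 3, 186842690 to 186858463), averaged 120 ± 107 CPM (SD, n = 4) in controls and 0.126 ± 0.0685 CPM (SD, n = 3) in CTEPH, a log2 fold change of -9.91 ± 1.08 (SE, adjusted p = 0.00315), which was -9.11 without Control 1 and -7.26 in the unstranded counts. RBP4, which encodes the retinol carrier, fell from 194 ± 131 to 0.169 ± 0.200 CPM, a log2 fold change of -10.15 (-11.42 without CTEPH 2). THRSP, a gene of fatty acid synthesis (chromosome 11, 78063861 to 78068351), had 1134 counts over the controls and 0 over the CTEPH libraries. Set against a floor of 3 counts over the CTEPH group, THRSP was at least 269.9-fold lower, and at least 172-fold without Control 1 or 159-fold without CTEPH 3. The same floor gave at least 143-fold for CKMT1B, a mitochondrial creatine kinase gene (84.2-fold without CTEPH 3). For ABCB11, the bile salt export pump gene, it gave at least 85.1-fold (50.1-fold without CTEPH 3), but in the unstranded counts ABCB11 had 9 counts in CTEPH and a ratio of 24.5 (12.8 to 53.96). Reads of CKMT1B cannot be assigned with certainty because CKMT1A is a nearly identical copy. WT1, a transcription factor of mesothelium, had 4332 counts in controls and 1 in CTEPH, a ratio of 2557 (459 to 101030). NWD2 had 1619 counts and 1 count, a ratio of 956 (171 to 37772), and a ratio of 98.5 in the unstranded counts. CTEPH 3 held the 1 count of both genes, and without it they were at least 548-fold and 197-fold lower. CXCR1, a neutrophil chemokine receptor gene, had 1357 counts and 1 count, a ratio of 801 (144 to 31663), but only 222 of the 1357 remained without Control 1. Its ratio was 161 (28.7 to 6399) without Control 1 and 472 without CTEPH 3, and without CTEPH 1 it was at least 237-fold lower. The acute-phase gene SAA1, which has a close copy in SAA2, fell 681-fold (1841-fold without CTEPH 3, 448-fold in the unstranded counts) and LBP, the lipopolysaccharide-binding protein gene, 665-fold. The calls of CXCR1 and THRSP were lost with limma-voom and without CTEPH 1, 2 or 3 (adjusted p at most 0.165 and 0.0667), those of CKMT1B and ABCB11 without CTEPH 3 (0.0554 and 0.0546) and that of LBP with limma-voom (0.161).

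**Figure D1:**
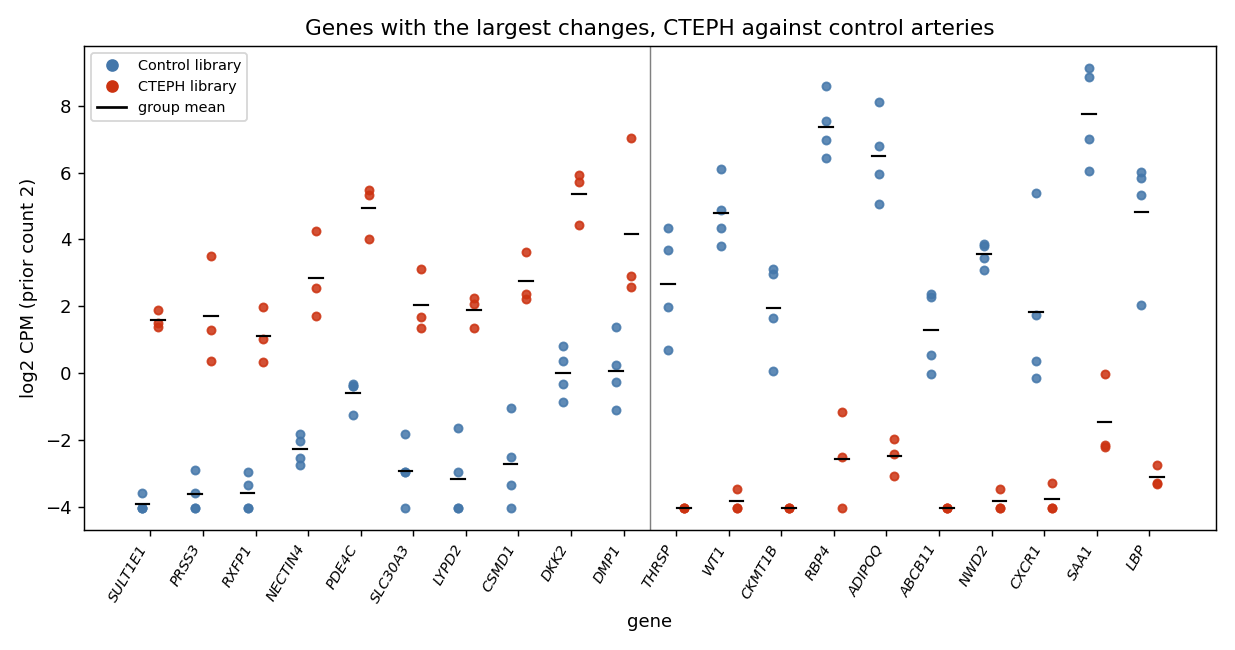
Log2 CPM (prior count 2, y axis) of the 10 genes with the largest increase and the 10 with the largest decrease (x axis, left and right of the grey line). Points are libraries, 4 control in blue and 3 CTEPH in red, and black bars are group means; in each gene the groups do not overlap.

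Genes of fat, nerve, mesothelium and the adventitia were tested as lists. All 16 adipocyte markers fell, with a median log2 fold change of -6.81. PLIN1, which coats lipid droplets, fell 116-fold from 303 ± 185 CPM (SD, n = 4), and GPD1, of glycerol phosphate synthesis, fell 397-fold (648-fold without CTEPH 3, 196-fold in the unstranded counts). The perilipin PLIN4 fell 109-fold from 838 CPM (70.8-fold in the unstranded counts). The camera adjusted p of this list was 4.56e-27 with the preset correlation, and adjusted p = 0.229 with an estimated correlation. All 11 Schwann cell and nerve markers fell, with a median of -4.87 (camera adjusted p = 3.04e-18, and adjusted p = 0.0598 with an estimated correlation). The Schwann cell cadherin CDH19 fell 29.2-fold (54.4-fold without CTEPH 2) and S100B 19.2-fold. Of 13 mesothelial and lymphatic markers, 9 fell and none rose, with a median of -3.75 (camera adjusted p = 2.47e-14, and adjusted p = 0.0598 with an estimated correlation). Limma-voom called 5 of the mesothelial or lymphatic, 11 of the adipocyte and 9 of the Schwann cell members. Podoplanin (PDPN) fell 85.8-fold and the hyaluronan receptor LYVE1 13.4-fold, from 189 ± 36.9 to 14.1 ± 5.11 CPM. The adventitial fibroblast list had 8 lower and 1 higher of 18 members and a median of -1.29 (camera adjusted p = 3.3e-06, and adjusted p = 0.338 with an estimated correlation). IGF1 fell 49.8-fold, the adipsin gene CFD 46.9-fold and the ferritin receptor gene SCARA5 74.8-fold (172-fold without CTEPH 2). Over these lists, 16 adipocyte, 11 Schwann cell, 10 mesothelial or lymphatic and 11 adventitial members were lower when adjusted over the list alone, and 2 adventitial members were higher.

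**Figure D2:**
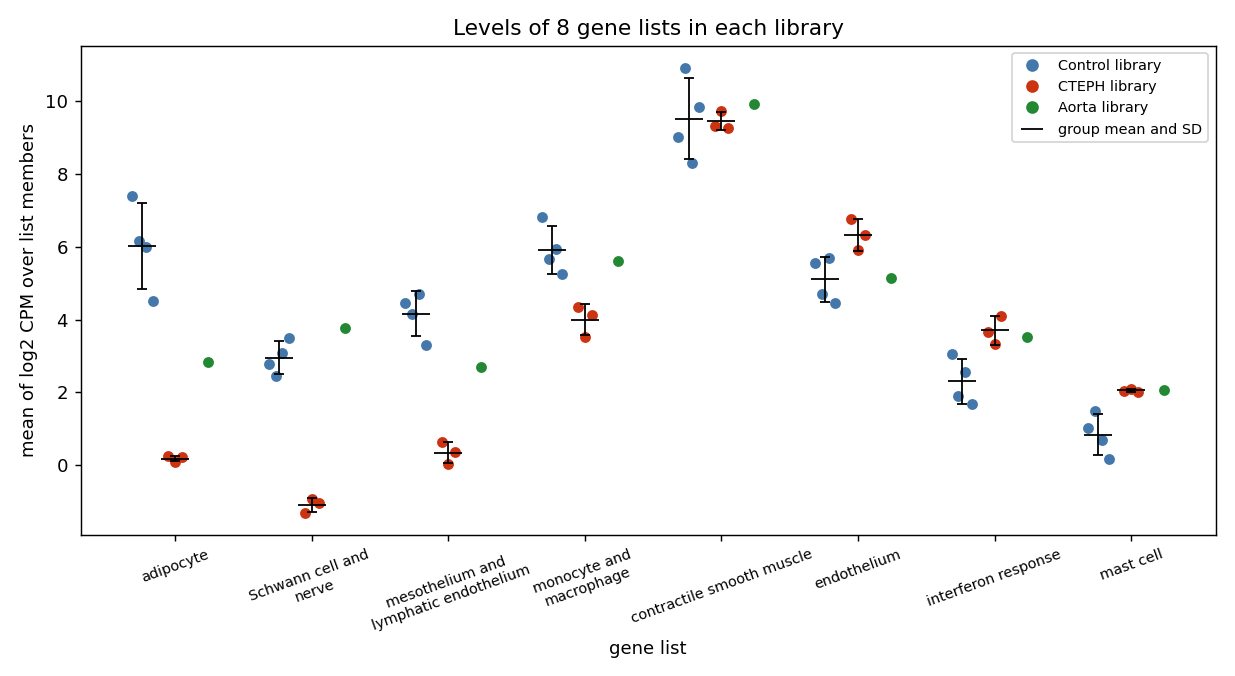
Mean log2 CPM over the members of 8 gene lists (y axis) in each library, with control libraries in blue, CTEPH in red and the aorta in green; black bars are group means with SD. The adipocyte mean was 4.51 to 7.39 in the controls, 0.0919 to 0.242 in CTEPH and 2.84 in the aorta, while contractile smooth muscle overlapped between the groups (8.31 to 10.9 and 9.27 to 9.72).

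Leukocyte, complement and haem-handling genes were tested next. The monocyte and macrophage list had 10 of 19 members lower and a median of -2.02 (camera adjusted p = 1.18e-12, and adjusted p = 0.338 with an estimated correlation). The haemoglobin scavenger receptor gene CD163 (chromosome 12, 7470813 to 7503893) fell 17.95-fold from 690.5 ± 149.7 to 38.5 ± 13.5 CPM, with VSIG4 and MARCO falling 9.15-fold and 35.4-fold. The neutrophil list had 7 of 14 members lower and a median of -5.28 (camera adjusted p = 8.13e-06, and adjusted p = 0.531 with an estimated correlation). The calprotectin genes S100A8 and S100A9 fell 146-fold and 45.8-fold, and the formyl peptide receptor gene FPR1 27.2-fold. Without Control 1 these folds were 48.1, 18.4 and 12.3, and without CTEPH 1 they were 486, 102 and 40.8. Over the 14 tested members Control 1 had a mean of 5.53 log2 CPM and the other controls 1.76 to 2.31, and the list was still called without it, but of its members DESeq2 called 8 and limma-voom 0. The calls of S100A8, S100A9 and FPR1 were lost in 5 alternative settings each, among them limma-voom and the fits without CTEPH 1, 2 or 3. Complement genes fell in 9 of 20 cases with a median of -1.53 (camera adjusted p = 1.02e-06, and adjusted p = 0.338 with an estimated correlation). C3 fell 76.3-fold, from 5500 ± 3141 to 72.1 ± 31.4 CPM, and C1S fell 3.79-fold. Haem and iron handling had 7 lower and 1 higher of 16 members and a median of -1.41 (camera adjusted p = 6.11e-06, and adjusted p = 0.28 with an estimated correlation). Haptoglobin (HP) fell 429.8-fold (208-fold without Control 3, 714-fold without CTEPH 3 and 151-fold in the unstranded counts) and the transferrin receptor gene TFRC 5.18-fold. The lipid-laden macrophage list had 5 of 18 members lower and a median of -0.85 (camera adjusted p = 0.000469, and adjusted p = 0.531 with an estimated correlation). It shares 4 members with other lists, and its lead genes LPL (123-fold lower, 203-fold without CTEPH 1), FABP4 (104-fold, 63.98-fold without Control 1) and PLIN2 (6.61-fold) are also abundant in fat. The mast cell list was higher, with 3 of 11 members called and a median of 1.09 (camera adjusted p = 0.000606, and adjusted p = 0.338 with an estimated correlation). The IgE receptor subunit MS4A2 rose 5.89-fold (9.86-fold without Control 2), histidine decarboxylase (HDC) 3.41-fold and GATA2 2.46-fold, and these calls were lost in 6, 6 and 4 of 22 alternative settings, among them the fits without CTEPH 1, 2 or 3. When adjusted over the list alone, 16 macrophage, 12 neutrophil, 11 complement, 11 haem and iron and 6 lipid-laden macrophage members were lower, 1 haem and iron and 1 lipid-laden macrophage member was higher, and 4 mast cell members were higher.

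Lymphocyte, red cell and platelet lists did not pass the test. The T and NK lymphocyte list had 0 of 19 members called and a median of -0.46 (camera adjusted p = 0.686), with IL7R at -2.23 ± 0.71 (SE). The B lymphocyte and plasma cell list had 0 of 11 called and a median of -1.45 (camera adjusted p = 0.54), with JCHAIN at -2.57 ± 1.34 and CD22 at -1.45 ± 0.86 (-0.45 and -0.27 without Control 3, and CD22 at -2.17 without CTEPH 3). Among 7 erythroid genes 1 was lower, EPB42, with 475 and 3 counts, a ratio of 93.5 (31.8 to 455), and the list median was -2.53 (camera adjusted p = 0.151). The platelet list had 0 of 5 called and a median of -2.16 (camera adjusted p = 0.303), with GP1BA at -2.68 ± 1.05 and TUBB1 at -2.93 ± 1.23 (1.01 and -0.49 in the unstranded counts, and TUBB1 at -0.81 without Control 1). Lung epithelial markers had 2 of 8 lower, CDH1 (14.7-fold) and SLC34A2 (13.1-fold), both at or under 1.47 CPM in controls, with a list median of -0.19 (camera adjusted p = 0.412). Cardiomyocyte markers had 0 of 10 called (median -0.48, camera adjusted p = 0.506), with TTN at -1.95 ± 0.60 and ACTC1 at -3.52 ± 1.58, where Control 2 had 10.4 log2 CPM of ACTC1 and the other controls 4.64 to 5.2. Without Control 2, ACTC1 was at -0.02, and TTN was at -0.91 in the unstranded counts. The edgeR test gave an unadjusted p under 0.05 for 1 T and NK, 0 B cell, 2 platelet and 1 cardiomyocyte member, DESeq2 called 1, 0, 1 and 1 of them, and limma-voom called 0 in each list. The erythroid list passed without Control 4 (camera adjusted p = 0.0083) and the cardiomyocyte list without CTEPH 2 (0.0441). Adjusted over the list alone, 0 members of the T and NK, B cell, platelet and cardiomyocyte lists were called, and 1 erythroid and 2 lung epithelial members were lower. The calls of EPB42, CDH1 and SLC34A2 were lost in 3, 5 and 4 alternative settings, among them the unstranded counts and the fit without CTEPH 3, where SLC34A2 was 27.2-fold lower. In the unstranded counts the 3 were 3.82-fold (by ratio), 6.32-fold and 3.82-fold lower.

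Endothelial and interferon-response lists had positive medians. The endothelial list had 10 higher and 1 lower of 19 members and a median of 1.58 (camera adjusted p = 5.47e-07, and adjusted p = 0.456 with an estimated correlation). CALCRL, part of the adrenomedullin receptor, rose 4.21-fold from 60.3 ± 22.8 to 254 ± 50.2 CPM. The vascular phosphatase gene PTPRB rose 4.999-fold and the junction gene ESAM 3.28-fold, a call lost without CTEPH 1, 2 or 3 (adjusted p at most 0.0694). PLVAP, a component of endothelial fenestrae, was the member that fell, by 1.99 on the log2 scale from 39.8 CPM. The interferon list had 9 of 23 members higher and none lower, with a median of 1.57 (camera adjusted p = 1.6e-09, and adjusted p = 0.338 with an estimated correlation). IFI44L rose 8.98-fold, the antiviral gene RSAD2 7.45-fold and MX1 3.18-fold, from 35.2 ± 7.81 to 112 ± 28.3 CPM. In a test adjusted over the list alone, 12 endothelial members were higher and 2 lower, and 11 interferon members were higher.

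Signalling and coagulation lists held both higher and lower members and did not pass the test. Of 23 coagulation and fibrinolysis genes, 3 were higher and 2 lower (median -0.17, mean -0.15, with the camera statistic upward, adjusted p = 0.686). The protease inhibitor gene SERPINE2 (ENSG00000135919, chromosome 2, 223975112 to 224039319) rose 14.7-fold, from 36.7 ± 3.99 to 539.8 ± 216 CPM. Tissue factor (F3) fell 4.86-fold and the factor XIII subunit F13A1 4.93-fold. Control 1 had a mean of 7.08 log2 CPM over the 23 tested members and the other controls 6.1 to 6.25. Von Willebrand factor (VWF) was among the higher members, at 1566 CPM in controls and 5437 CPM in CTEPH. Vasoactive mediators and ion channels had 4 higher and 2 lower of 25 members (median 0.49, mean -0.05, camera adjusted p = 0.374). GUCY1B1, a subunit of the nitric oxide receptor guanylate cyclase, rose 3.30-fold. The angiotensin receptor gene AGTR1 fell 10.98-fold. In TGF-beta and BMP signalling 3 were higher and 2 lower of 25 (median 0.34, camera adjusted p = 0.124). The inhibitory SMAD6 rose 5.11-fold, and the receptor genes TGFBR2 and TGFBR3 fell 2.42-fold and 2.46-fold. Of 13 pulmonary arterial hypertension risk genes, 1 was called, TBX4, which rose 9.42-fold from 0.514 to 4.87 CPM (list median 0.53, camera adjusted p = 0.0901). The risk list passed in 5 of 23 other settings, which were no filter (0.0346), 2 CPM in 3 libraries (0.0428) and the fits without Control 1, CTEPH 2 or CTEPH 3 (0.0496, 0.0433 and 0.0323). TGF-beta and BMP signalling passed without Control 1 (0.0233). Without CTEPH 3 the call of TGFBR2 was lost, and without CTEPH 2 that of TBX4. Adjusted over the list alone, the calls were 3 higher and 2 lower for coagulation, 6 and 2 for vasoactive genes, 3 and 3 for TGF-beta and BMP, and 1 and 0 for the risk genes.

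Among wall and matrix genes, contractile smooth muscle had 1 of 20 members called (median -0.11, camera adjusted p = 0.75). That member was the intermediate filament gene desmin (DES), which fell 15.8-fold from 717 ± 445 to 45.3 ± 15.95 CPM. The matrix protease and inhibitor list was lower, with 4 of 19 members called and a median of -1.15 (camera adjusted p = 4.26e-05, and adjusted p = 0.456 with an estimated correlation). The protease inhibitor gene TIMP4 fell 12.1-fold, MMP19 7.61-fold (4.36-fold without Control 1) and cathepsin B (CTSB) 2.69-fold. Fibrillar collagen and fibrosis genes had 1 higher and 4 lower of 20 (median -0.29, camera adjusted p = 0.199). The sulfatase gene SULF1 rose 5.61-fold to 1602 ± 245 CPM, while COL6A3 fell 4.94-fold and ADAM12 10.1-fold. Elastic fibre and basement membrane genes had 1 higher and 8 lower of 20 (median -0.78, camera adjusted p = 0.0542), and this list passed without Control 3, Control 4 or CTEPH 2 (0.0169, 0.0171 and 0.0433). LAMA2 fell 4.87-fold and COL4A1 2.38-fold, and COL18A1 rose 2.46-fold. Osteochondrogenic genes had 1 higher and 2 lower of 16 (median -1.04, camera adjusted p = 0.295). The cartilage proteoglycan aggrecan (ACAN) rose 10.7-fold from 75.6 ± 54.7 to 810.2 ± 436 CPM, while CILP fell 85.6-fold (44.7-fold without Control 1) and SOX9 4.39-fold. In these lists, the calls of COL6A3, ADAM12, COL4A1, MMP19, CTSB, CILP, SOX9 and ACAN were lost in 2, 1, 1, 5, 2, 4, 4 and 6 of 22 alternative settings, each time with at least 1 fit without a CTEPH library among them. Adjusted over the list alone, 1 contractile member was lower, 1 matrix protease member was higher and 8 lower, 1 collagen member was higher and 4 lower, 4 elastic fibre members were higher and 11 lower, and 2 osteochondrogenic members were higher and 2 lower.

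Metabolic, stress-response, inflammatory and cell cycle genes were tested as well. Hypoxia and glycolysis had 6 of 19 members lower and a median of -0.75 (camera adjusted p = 0.00157, and adjusted p = 0.338 with an estimated correlation). Hexokinase 2 (HK2) fell 9.93-fold, LDHA 2.52-fold and ENO1 2.34-fold. Oxidative phosphorylation had 3 of 23 lower and a median of -0.35 (camera adjusted p = 0.0208, and adjusted p = 0.592 with an estimated correlation). Cytochrome c (CYCS) fell 2.56-fold, ATP5F1B 1.73-fold and COX5A 1.86-fold, and the calls of ATP5F1B and COX5A were lost in 11 and 13 of 22 alternative settings. This list's own call was lost without Control 1 and without CTEPH 3 (adjusted p at most 0.0964). Immediate early and heat shock genes had 4 of 24 lower and a median of -1.12 (camera adjusted p = 0.000689, and adjusted p = 0.531 with an estimated correlation). This list had been fixed as a measure of sample quality, and differences in sample handling were not tested. FOS fell 6.22-fold, MYC 5.42-fold (3.58-fold without Control 1) and HSPH1 1.97-fold. The inflammatory list had 2 of 21 lower, IL6 (55.2-fold, 24.2-fold without Control 1) and CXCL1 (7.76-fold, 4.11-fold without Control 1 and 11.7-fold without CTEPH 3), and a median of -1.49 (camera adjusted p = 0.0561). It passed without Control 2, 3 or 4 or CTEPH 1 (0.0229, 0.0129, 0.0174 and 0.0311). Its mean over the 21 tested members was 5.29 log2 CPM in Control 1 and 2.71 to 3.15 in the other controls, and the calls of IL6 and CXCL1 were lost in 5 and 12 of 22 settings. The calls of FOS, MYC, HSPH1, LDHA and ENO1 were lost in 3, 5, 4, 1 and 2 settings, among them the fit without CTEPH 3. Cell cycle genes had 0 of 21 called with edgeR, 0 at an unadjusted p under 0.05, and 0 with DESeq2 or limma-voom, a median of -0.26 and an upward camera statistic (adjusted p = 0.75), with AURKA at -0.75 ± 0.35 and MCM6 at -0.38 ± 0.19. Adjusted over the list alone, 7 hypoxia and glycolysis, 5 oxidative phosphorylation, 12 stress-response and 8 inflammatory members were lower, 1 inflammatory member was higher and 0 cell cycle members were called.

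In all, 16 of 32 lists had a camera adjusted p under 0.05 with the preset correlation of 0.01, 3 of them higher and 13 lower. With a correlation estimated for each list, 0 passed and 4 had an unadjusted p under 0.05, and fry, which tests whether a list's genes move in one direction without comparing them with other genes, called 10. Of the 35 splits of the 7 libraries into 3 and 4, 22 called 16 or more lists with the preset correlation, the real split included. Numbers of called members depended on the tool by over 1.5 times in further lists. DESeq2 called 13 immediate early, 10 matrix protease, 9 inflammatory, 14 elastic fibre, 8 coagulation, 8 TGF-beta and BMP, 8 lipid-laden macrophage and 5 oxidative phosphorylation members, 2 contractile and 2 risk genes, and limma-voom called 2 matrix protease, 1 inflammatory, 1 lung epithelial and 0 erythroid members. Several members stand in more than 1 list, among them 6 of 20 complement and 4 of 20 endothelial genes.

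**Figure D3:**
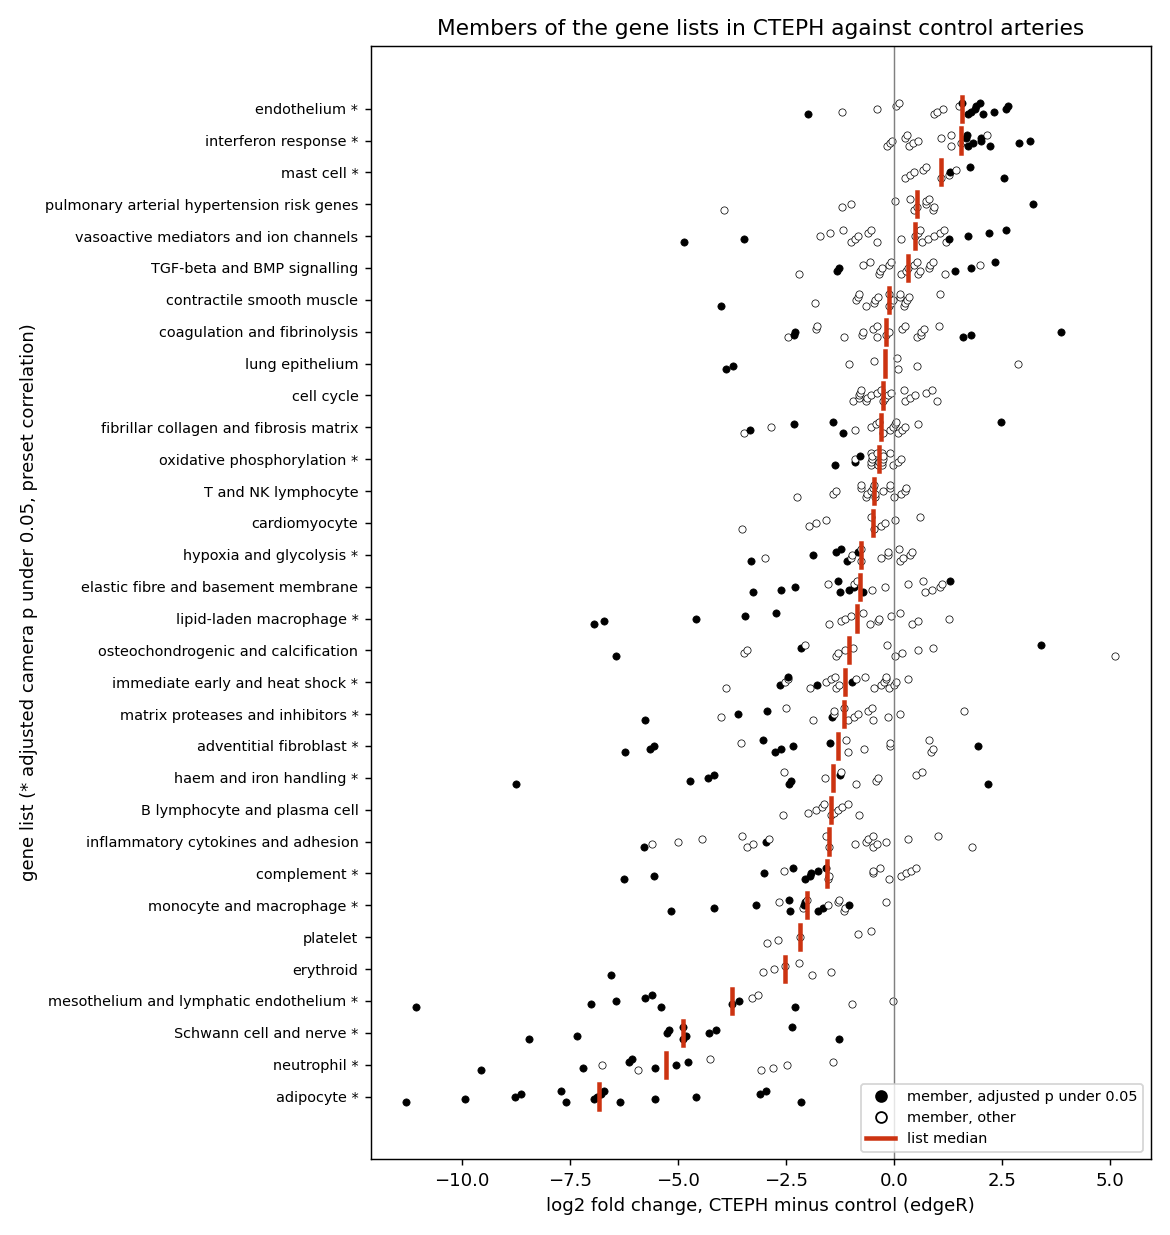
Log2 fold change of each tested member (x axis, CTEPH minus control) of the 32 gene lists (y axis), ordered by list median (red bars); filled points had an edgeR adjusted p under 0.05 and asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation. Medians ran from -6.81 for adipocyte genes to 1.58 for endothelial genes.

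The aorta was set beside the control pulmonary arteries to describe how this library differs from them. As 1 library has no replicate, values are given without a test, and the vessel cannot be told apart from the sample. Its correlations with the controls were 0.925 to 0.935, inside the range between controls (0.918 to 0.958). The mean log2 CPM of T and NK lymphocyte genes was 3.10 in the aorta and at most 2.67 in a control, and that of immediate early and heat shock genes 7.41 and at most 6.67. Means of adipocyte, mesothelial or lymphatic and cardiomyocyte genes were 2.84, 2.71 and 0.74 and lay below the lowest control (4.51, 3.31 and 1.05). Of 17631 genes compared, 1632 lay outside all 7 pulmonary artery libraries and at least 2-fold from the control mean, 1217 above and 415 below. At any size of difference, 26.1% of genes lay outside all 7, and chance gives 25%. KRT17, a keratin gene, had 43.3 CPM in the aorta and 1.34 ± 0.948 CPM (SD, n = 4) in the controls. The interferon-induced chemokine genes CXCL9 and CXCL10 had 11.8 and 9.19 CPM in the aorta and 0.495 ± 0.483 and 0.438 ± 0.692 CPM in controls. The death ligand gene FASLG had 6.62 CPM against 0.388 ± 0.591 CPM. The other genes with the largest excess were DCC at 22.9 CPM, TMEM130 at 27.3 CPM, USP6 at 22.4 CPM and CCL3L1 at 24.8 CPM. In controls they averaged 2.49 ± 3.49, 1.51 ± 1.58, 1.36 ± 2.49 and 0.620 ± 0.421 CPM. DCC and USP6 reached 7.62 and 5.09 CPM in a control, and TMEM130 had 16.1 to 21.1 CPM in CTEPH arteries. USP6 has close relatives in the genome, and CCL3L1 differs in copy number between people. Among the genes lower in the aorta, cardiac myosin MYH6 had 0 counts in the aorta and 18.1 ± 31.2 CPM in the controls. Its values ran from 0.296 to 64.8 CPM in the controls and from 0.123 to 15.4 CPM in the CTEPH libraries. The lipid-regulating ANGPTL8 had 3 counts in the aorta and 11.2 ± 7.94 CPM in controls. The T-box factor TBX5 (chromosome 12, 114353931 to 114408442) had 0.682 CPM in the aorta, 5.65 ± 2.74 CPM in controls and 41.5 to 95.1 CPM in CTEPH arteries. TCF21, a mesenchymal transcription factor gene, had 0.722 CPM against 8.69 ± 4.16 CPM. The serotonin transporter gene SLC6A4 had 0.441 CPM against 5.11 ± 3.09 CPM, and STAC2, GABRR1 and ACTA1 were also lower.

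Gene lists in the aorta were placed by their median difference from the control mean among 10000 random lists matched on size and mean expression. B lymphocyte genes (median log2 difference 2.16), immediate early and heat shock genes (1.69), T and NK lymphocyte genes (1.66), inflammatory genes (1.25), interferon genes (0.98) and elastic fibre genes (0.44) stood at the 100th percentile. Mast cell (1.05), osteochondrogenic (0.91), Schwann cell (0.88), fibrillar collagen (0.42), contractile smooth muscle (0.36) and TGF-beta and BMP genes (0.26) stood above the 99th. Adipocyte (-3.22), mesothelial and lymphatic (-1.48), cardiomyocyte (-1.27), neutrophil (-0.81) and oxidative phosphorylation genes (-0.55) stood at percentile 0. Leaving out 1 control moved several of these medians by over 1.5 times. The osteochondrogenic median was 0.46 without Control 1 or 3, fibrillar collagen 0.25 without Control 3, elastic fibre 0.25 and TGF-beta and BMP 0.14 without Control 4, and contractile smooth muscle 0.22, 0.79 and 0.05 without Control 1, 2 and 3. The B lymphocyte median was 3.44 without Control 3, and without Control 1 the inflammatory and neutrophil medians were 1.89 and -0.07. Of the lists between the extremes, lung epithelium had a median of 0.45 and platelet genes 0.97 (1.89 without Control 1). Erythroid genes had 0.68 (1.33 without Control 1, and 0.30 without Control 3 or 4) and cell cycle genes 0.35 (0.53, 0.77 and 0.05 without Control 1, 3 and 4). Matrix protease genes had -0.27 (-0.53 without Control 3), haem genes -0.31 (-0.11 without Control 1) and hypoxia genes -0.11 (-0.02, -0.04, -0.39 and -0.20 without Control 1 to 4). The medians of 9 lists turned sign with the control left out and are given with their lowest and highest value over these 4 choices. They were adventitial fibroblast (0.22, from -0.07 to 0.39), vasoactive (0.23, from -0.003 to 0.35), endothelial (0.14, from -0.09 to 0.35), coagulation (0.07, from -0.09 to 0.16), lipid-laden macrophage (0.09, from -0.20 to 0.22), risk gene (0.10, from -0.12 to 0.07), regional identity (0.02, from -0.34 to 0.04), macrophage (-0.09, from -0.26 to 0.16) and complement medians (-0.16, from -0.25 to 0.10). These percentiles come from random lists and do not cover the spread between libraries. The means given for the aorta and its control ranges were taken over members kept with all 8 libraries (16 neutrophil and 24 inflammatory genes), so they differ from the means of tested members above. Among the lists at the extremes, the aorta's mean lay inside the control range for B lymphocyte (2.30 in -2.10 to 2.73), inflammatory (4.04 in 2.08 to 4.62), elastic fibre (8.86 in 8.4 to 9.02), neutrophil (1.58 in 1.16 to 4.86) and contractile smooth muscle genes (9.92 in 8.31 to 10.9). None of the 20 contractile members lay outside all 7 libraries. A filter of 2 CPM in 1 library lowered the count of outlying genes to 933.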

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

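The library properties among the checks below were chosen after the data had been seen, and the genes and lists by rules fixed beforehand. Among 139 measures checked in the 4 control libraries (named genes, list means and library properties), 8 had 1 library far from the other 3. Chance gives about 5% of such checks; the CTEPH group of 3 was not checked. The values below are the gap to the nearest library divided by the range of the group. List means were taken over the members tested between CTEPH and control arteries. Control 1 was highest for the neutrophil list (gap share 0.854, mean log2 CPM 5.53 against 1.76 to 2.31), the inflammatory list (0.831, 5.29 against 2.71 to 3.15) and the coagulation list (0.853, 7.08 against 6.1 to 6.25). Control 2 was highest for ACTC1 (0.902, 10.4 against 4.64 to 5.2). Control 4 was lowest for PDE4C (0.939, -1.26 against -0.39 to -0.33) and SOX9 (0.838, 5.39 against 6.55 to 6.77). It was also highest for SULT1E1 (gap share 1), where it held the 1 count found in the controls. Control 3 had the highest share of immunoglobulin and T cell receptor counts (0.847, 3.48% against 0.0274% to 0.554%).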

How the results depend on the processing

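The length and GC trend removal, the removal of immunoglobulin genes and the thinning of libraries to 1 depth were chosen after the data had been seen, and the trend was fitted anew, robustly and centred on 0, after a first least-squares version had recentred each library. No list or named gene that was called changed direction in any setting tried. The count of called genes, 1740, was 1471 to 2172 under the other tools, scalings, filters, columns and covariates except 2. DESeq2 called 3322, of which 1729 were among the 1740, over 18014 genes against 15696 with edgeR. The cause was not tested. On simulated counts 25.5% of its calls were false. Few genes were changed there and edgeR's dispersions were used, so this share cannot be read onto the 3322. Requiring a change beyond 1.5-fold gave 764, a stricter question by construction. Leaving out 1 library gave 430 to 1819 genes. The counts were 652, 552 and 430 without CTEPH 1, 2 and 3, where 2 CTEPH libraries remained. In all 7 of these fits 367 calls were kept. Thinning every library to the smallest total gave 1715 calls, 1628 of them shared, and removing the length and GC trend gave 1881, with 1673 shared. With library sizes only, the median log2 fold change of all genes moved from -0.02 to 0.08 and the share of higher calls from 35.3% to 44.9%. The count of lists, 16, was 16 to 19 in the other settings and on leaving out any library, but 0 with an estimated correlation, which widens the variance for correlated members, and 10 with fry, which asks another question. Of 90 called genes chosen by the naming rules, 37 lost the call in at least 1 setting, 14 of these only when a library was left out. Of lists not called, the elastic fibre, inflammatory and risk gene lists passed in 11, 9 and 5 of 23 settings, and the TGF-beta, erythroid and cardiomyocyte lists in 1 each. The oxidative phosphorylation list lost its call in 4 of 23 settings, among them the fits without Control 1 and without CTEPH 3. The 1632 outlying genes of the aorta became 933 with a filter of 2 CPM in 1 library, where fewer genes were compared, and 1620 to 1968 on leaving out a control. Depth limits genes with few counts, and 3 CTEPH libraries limit the detection of changes near 2-fold.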

Other observations

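The genes of the next 2 paragraphs were chosen after the data had been seen, as were the tests of the 2 patterns weighed below; the splits of the libraries were planned. Several of these tests replaced a first version after its result: the adipocyte, nerve and mesothelial markers were first tested on the lists' own members, all leukocytes were first tested together and left open, and the endothelial share was first tested by a permutation alone. For wall dilution and leukocytes, bounds on list means (2 SE, a t distribution, exact permutation) came before the test on members used below; all 3 had left lymphocytes open, and the last 2 also dilution. Of 15 HOX genes tested 6 were higher in CTEPH and 0 lower, with a family median log2 fold change of 1.56 (1.56 to 1.65 under other scalings). HOXA10 rose from 0.489 ± 0.239 CPM (SD, n = 4) to 6.14 ± 2.16 CPM (SD, n = 3), with an edgeR adjusted p of 0.00792, and HOXB3 from 14.3 to 39.3 CPM. The T-box genes TBX2 (13.3 to 103 CPM), TBX4 and TBX5 (5.71 to 73.5 CPM) rose, while TBX20 fell from 45.4 to 4.64 CPM.

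Of 13 Notch receptors, ligands and HES or HEY targets tested, 5 were called higher, 0 lower and 8 in neither direction, among them HES1 at -0.75 and DLL1 at 0.39 (median 1.05, and 1.05 to 1.18 under other scalings). This set was not tested as a list, and the endothelial list had a median of 1.58. JAG1 rose from 543 ± 21.1 to 2316 ± 349 CPM (adjusted p = 0.00154), NOTCH3, the smooth muscle Notch receptor, from 529.8 to 1101 CPM, and HEY2 from 19.8 to 85.2 CPM. The arterial connexin GJA5 rose from 109.6 to 687.7 CPM. Of 7 metallothioneins 4 fell (median -3.18, and -3.18 to -3.09 under other scalings), with MT1A at 65.3 and 0.464 CPM; these genes are close copies of one another. The lipid synthesis genes FASN and SCD fell from 3500 to 104.8 CPM and from 638 to 10.5 CPM, beside a median of -6.81 for the adipocyte list, and no list of such genes was tested.

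Among the 35 splits of the 7 libraries into 3 and 4, the real one called 1740 genes with edgeR. The highest other split called 0. This argues against a random division of the libraries as the source of the gene calls, though 1 of 35 is the smallest share possible. Every other split mixed CTEPH and control libraries in at least 1 group, which widens the spread within it. The splits cannot speak to other differences between the samples that run with the groups. For lists, 22 of the 35 splits called as many lists with camera as the real 16, and the highest other split called 25. The number of lists past the threshold at the preset correlation therefore cannot be set apart from these other divisions of the libraries. Other splits can carry part of the real contrast. The split with 25 lists set Controls 1, 2 and 4 against all other libraries. For lists, the splits are thus not a pure measure of chance.

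The first pattern was the loss of adipocyte, Schwann cell and mesothelial or lymphatic transcripts. Removing length and GC trends left the median of the members at -5.36, beside -5.32 before, which argues against such a bias. A candidate explanation is that the control samples held more tissue from around the artery. Of 48 further markers of these cells, 28 stood in a fixed list or were not tested. Of the other 20, 19 (95%) were lower in CTEPH and 14 of them were called, while DHH rose. Among the 8 Schwann cell markers of these, 4 were called lower. A loss of these cells in disease would lower the same markers, so they cannot tell the 2 explanations apart. Dilution of wall RNA by tissue from around the artery, as the whole cause of the increases, needs contractile smooth muscle members to rise by about 1.39. This is the median of the higher genes. The members' median plus SD was 0.932 and their highest 1.07, and 2 of 4 controls exceeded every CTEPH library in this list's mean. That SD is a spread between genes and does not cover the spread between libraries. The group change of -0.0784 ± 0.57 (SE) had an upper bound of 1.06 with 2 SE and a wide upper 95% permutation bound of 2.70. As the latter lies above 1.39, this group change alone cannot decide. In Controls 2 and 4 the contractile list stood at 10.9 and 9.85 log2 CPM, above every CTEPH library (at most 9.73). In Controls 1 and 3 it stood at 9.03 and 8.34, below every CTEPH library. Yet the genes called higher averaged 2.63 to 2.89 in all controls and 4.42 to 4.5 in CTEPH. Taking this list as a measure of wall RNA, these levels argue against dilution as the whole of the increases. Dilution stays open as a part. Between 3 and 8 members of these 3 lists reached 1 CPM in CTEPH, 3 adipocyte members stand in other lists, and a loss of these cells in disease stays open and was not tested.

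The second pattern was the rise of interferon-response genes, with a list median of 1.57. More macrophages or neutrophils are argued against as the whole cause, since the members' median plus SD was at most -0.862. The upper permutation bounds of these 2 list changes were -0.359 and -1.15. For lymphocytes the members' median plus SD was at most 0.162, with no T and NK or B cell member above 0.28. That SD is a spread between genes and does not cover the spread between libraries. Controls 1 and 3 held more T and NK transcripts (2.49 and 2.90 log2 CPM) than any CTEPH library (at most 1.85) but less of the interferon list. The group changes of T and NK and B cell genes, -0.116 ± 0.753 and -0.487 ± 1.31 (SE), had wide upper permutation bounds of 3.21 and 4.58. Both bounds lie above 1.57, so these group changes alone cannot decide. The interferon mean was 3.29 and 2.86 in Controls 1 and 3 and 3.59 to 4.34 in CTEPH. With the T and NK levels above, this argues against T and NK lymphocytes as the whole cause. In Controls 2 and 4 both were low (T and NK 0.153 and 0.789, interferon 2.18 and 1.93), so they stay open as a part. For B cell genes only Control 3 (3.67) exceeded every CTEPH library (at most 1.46), so B cells stay open as a part or the whole. A larger endothelial share cannot be told apart, since the interferon and endothelial means rose together, their difference changing by 0.188 ± 0.257 (exact permutation p = 0.429, two-sided, smallest possible 0.0286). Against it as the whole cause, 26.3% of endothelial members (5 of 19, among them KDR, PLVAP and ERG) lay more than 2 SE below the interferon median, but the limit of 25% was set after the first test and 1 member decides it, and an interferon response to disease also stays open as a hypothesis.

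In the list of regional identity factors, fixed beforehand for the aorta, 12 of 28 tested members were called, 8 higher and 4 lower (42.9%, against 11.1% of all genes). The list holds 13 HOX and 6 T-box genes, which gave 9 of the 12 calls and had drawn attention to it, so a Fisher test of it was dropped; of the other 9 members 3 were lower. The labels give no position in the pulmonary tree, and what separates the groups in these genes was not tested.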
